A study of Homo sapiens with 6 samples.

How the data were processed

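RNA from 6 xenograft tumours was hybridised to a human 3' expression array of 54675 probe sets, 1 array per tumour. The groups and replicate numbers come from the sample titles, and the dose and times from the treatment labels. Untreated controls, tumours taken 6 h after PU-H71 and tumours taken 12 h after it have 2 arrays each. Per the labels, total RNA was extracted with a column kit, its integrity was checked on a chip, and biotinylated cRNA was prepared with the array maker's standard protocol. The deposited values are on the log2 scale, and per the submitters' processing notes the authors made them with RMA, which corrects background, quantile-normalizes the arrays and summarises the probes of each set. The RMA implementation, its version, its annotation and whether the 6 arrays were normalized together or with other arrays are not given in the sources used here. Column medians ran from 6.56 to 6.59, and 0 values were missing. The closest arrays correlated at 0.996 over all probe sets. Since the values are log2, no pseudocount was needed and the alternative planned for linear values was not applicable. Arrays have no read depth, and the number of arrays sets the precision.

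Probe sets were named with the array platform's annotation table, and symbols were updated through Entrez IDs with a RefSeq gene table of assembly GRCh38.p14, used for names and gene classes. Of the probe sets, 41097 had 1 gene symbol, 1801 had several and 11777 were not listed there. Of those with 1 symbol, 41043 were matched to the gene table. Probe sets with several symbols named no gene. HSPA1A and HSPA8, which were to be named in any case, have only such probe sets and are not reported by name. The 62 control probe sets were left out of the tests. Each gene took the probe set with the highest mean over all 6 arrays, which gave 19775 genes. Genes with a mean under 6.19, the 40th percentile of all probe sets, were left out as dim, and 14768 were tested. Probe sets of 1 gene can disagree: in GNL3L the 4 probe sets changed between -0.60 and -0.14 at 6 h and between -0.26 and 0.91 at 12 h.

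Tests used limma 3.58.1 in R 4.3.3. A linear model with a mean per group was fitted to all 6 arrays (lmFit, eBayes), which leaves 3 residual degrees of freedom and borrows 3.8 from the other genes. Contrasts were 6 h against control, 12 h against control, 12 h against 6 h, and the mean of both times against control. P-values were two-sided, adjusted with Benjamini-Hochberg over the tested genes and called under 0.05. An exact permutation test of 2 arrays against 2 cannot go below p = 0.333, so none was used. In the text, "± SD" is the spread of the 2 arrays of a group and "± SE" the standard error of the fitted log2 change. The 29 gene lists (stress responses, B-cell programmes, cell cycle, metabolism and cell type markers) were fixed before the data were examined, as were the comparisons, the alternatives below and the rule for named genes. Each list was tested with limma's camera at a preset correlation of 0.01, with adjustment over all 116 tests of lists and contrasts. With the correlation estimated from the arrays, 0 of the 116 tests passed and 1 had an unadjusted p under 0.05. With fry, 0 passed for movement in 1 direction, with 19 at an unadjusted p under 0.05, and 31 for change in either direction. Fry does not compare a list with other genes. The median, the mean and the direction of the test differed in sign in 26 of the 116 tests and in 0 of the 29 that passed. Member counts are given over all genes and adjusted over the list alone.

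Named genes were the 10 largest increases and 10 largest decreases among passing genes whose arrays separated the groups, for 6 h and 12 h against control, and 5 and 5 for 12 h against 6 h. Where fewer qualified, the places were filled with the genes of smallest p in that direction, which are given as not passing. Up to 4 members of each list with the smallest p, BCL6 and the main chaperone genes could also be named. Other genes named in the text were chosen after their values were seen: HSF1, HSPBP1, CRYAB, and those of the closing observations that the rule does not give.

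The alternatives were no filter on dim genes, a filter at the 60th percentile, all probe sets tested separately, the mean of a gene's probe sets, and no probe sets of the _s_at and _x_at kinds. Others were repeated quantile normalization, centring on medians, an intensity trend in eBayes, only the arrays of the groups compared, the replicate number as a block, other thresholds, and leaving out each array in turn. Array weights and a crossed pairing were added after seeing the data. For the correlation of 6 h and 12 h changes, 100 sets of unchanged arrays were simulated with each gene's estimated SD, and 100 more for each array left out. The fit was tested on simulated data for the 6 h comparison over 14768 genes, with 50 genes changed at each fold. It recovered 98% of genes changed 2-fold and 100% of those changed 4-, 8- or 16-fold, and 13 of its 212 calls were unchanged genes. The simulation draws independent normal errors with the SDs estimated by the fit itself, which real arrays need not follow. In the arrays 49 genes rose and 66 fell at least 2-fold at 6 h, and 9 of these were called (limma). The simulated recovery is therefore no estimate of the share of real changes that the test finds. The difference between 3' and 5' control probe sets of actin and GAPDH and the mean of the 18S and 28S control probe sets describe RNA quality.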

Results

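Transcript levels were measured in 6 subcutaneous tumours grown from Farage cells, an established human diffuse large B-cell lymphoma line, in immunodeficient SCID mice. PU-H71, a purine-scaffold inhibitor of the chaperone HSP90, was injected into the peritoneum of 4 mice at 75 mg/kg. Tumours were taken 6 h later from 2 of these mice and 12 h later from 2, and 2 untreated mice served as controls. By the design each array came from its own mouse, so the spread within a group is between animals. Values are log2 RMA intensities for 54675 probe sets of a human whole-genome array. They gave 14768 tested genes, and the small number of arrays, n = 2 per group, limits the precision of every value. The arrays had nearly equal medians, from 6.56 to 6.59, and correlated with each other between 0.983 and 0.996 over all probe sets. Their upper quartiles were lower in the treated arrays, from 7.81 to 7.90, than in the controls, at 7.93 and 7.95. Part of the lower values of bright genes may come from this difference in scale. After repeated quantile normalization, which removes it, 27 of the 29 list calls were kept. Within pairs, the SD of the difference between the arrays was 0.198 for controls, 0.218 at 6 h and 0.291 at 12 h, on the log2 scale over the tested genes.

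The first question was which transcripts changed 6 h after the inhibitor. The heat shock list holds cytosolic chaperones, their partners and heat shock factor 1 itself. Of its 34 members, 28 had a value from a probe set with 1 gene symbol and were tested. Over all genes 4 of these rose and 24 did not pass. HSPB1, a small heat shock protein, rose 11.4-fold, from 9.20 ± 0.14 to 12.71 ± 0.49 (SD, n = 2; log2 change 3.51 ± 0.22 SE; adjusted p = 0.0164, limma). HSPA4L of the HSP110 family rose 3.55-fold, FKBP4, a peptidyl-prolyl isomerase that works with HSP90, rose 3.20-fold, and STIP1, which links HSP70 to HSP90, rose 2.62-fold. P4HA2, a subunit of the collagen prolyl 4-hydroxylase, rose 6.01-fold and PTOV1 rose 2.23-fold.

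In all, 11 of 14768 genes changed at 6 h in the limma test, 6 upwards and 5 downwards. Apart from HSPB1, each of the other 10 had adjusted p = 0.0463. The 5 that fell were MATR3, which encodes a nuclear matrix protein that binds RNA, the noncoding RNA SNHG4, EHD4, an endocytic ATPase, PDAP1 and the pseudogene SMG1P5. MATR3 fell by 2.13 ± 0.22 (SE) and SNHG4 fell by 1.62 ± 0.17 on the log2 scale. At 6 h SNHG4 was at 5.73 ± 0.06, under the dim threshold of 6.19, the 40th percentile of all probe sets, so the size of its change is uncertain. MATR3 and SNHG4 are each read here by 1 probe set, and 9 further probe sets for each carry several gene symbols, so which transcript changed is uncertain. SMG1P5 fell by 0.95 ± 0.09, and as a pseudogene with near-identical copies it is uncertain too. EHD4 fell by 1.24 ± 0.11, and PDAP1 fell by 0.95 ± 0.09. Among genes just short of the threshold, DNAJB4, a co-chaperone of HSP70, was at 5.86 ± 0.33 in controls and 8.18 ± 0.49 at 6 h (adjusted p = 0.0526), with the control level under the dim threshold. PRKACB, a catalytic subunit of protein kinase A, had a log2 change of 1.51 (adjusted p = 0.0520), TSPYL4 1.37 and LMAN2L 0.90. The lower genes named on the same terms were BHLHE41, a transcriptional repressor of the circadian clock, at -1.05, the splicing factor U2AF1 at -0.96, NUDT22 at -0.87, DLST of the 2-oxoglutarate dehydrogenase complex at -0.84 and ACAT2, a cytosolic thiolase, at -0.82. Their adjusted p-values ran from 0.0603 to 0.0636, so none of the 5 passed. The split of 6 up and 5 down became 34 up and 8 down after repeated quantile normalization and 1 up and 0 down with arrays centred on their medians. At adjusted p under 0.10 the count was 256 (87 higher, 169 lower). At adjusted p under 0.05, where all 6 arrays gave 11, limma called 0 without either control array, with 1206 and 1738 genes at an unadjusted p under 0.05, 1 without either 6 h array, and 273 without either 12 h array.

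The heat shock list shifted upwards at 6 h, with a median log2 change of 0.98 over 28 tested members (camera, adjusted p = 5.77e-22). This call was lost with a correlation estimated from the arrays (adjusted p = 0.779 with an estimated correlation). Of its members 4 rose, 0 fell and 24 did not pass over all genes. Adjusted over the list alone, 20 rose and 2 fell. Both 6 h arrays lay above both control arrays for 23 of the 28 members and below them for 2. Over all genes 56.9% were separated in either direction, where chance gives 33.3%. HSP90AA1 and HSP90AB1, the inducible and constitutive cytosolic HSP90 genes, were at 13.30 ± 0.02 and 13.42 ± 0.06 in controls. At 6 h they were at 13.94 ± 0.04 (adjusted p = 0.0843) and 13.96 ± 0.03 (adjusted p = 0.0886), and neither passed over all genes. The probe set used for HSP90AA1 changed by 0.64, the least of its probe sets, and the others by 0.71, 1.15 and 1.07. Those of HSP90AB1 that were not used changed by 0.41 and 0.54, against 0.54. DNAJB1, the main HSP40 co-chaperone, had a log2 change of 2.31 ± 0.31 (adjusted p = 0.0693), and HSPH1, an HSP110 chaperone, 2.01 ± 0.29 (adjusted p = 0.0843). The members lower in the test over the list alone were HSF1, the factor that activates this response, at -0.58, and HSPBP1, which inhibits HSP70, at -0.38. In the same arrays the difference between the 3' and 5' probe sets of actin was higher at 6 h (0.11 ± 0.04, SD) than in controls (-0.11 ± 0.05).

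**Figure D1:**
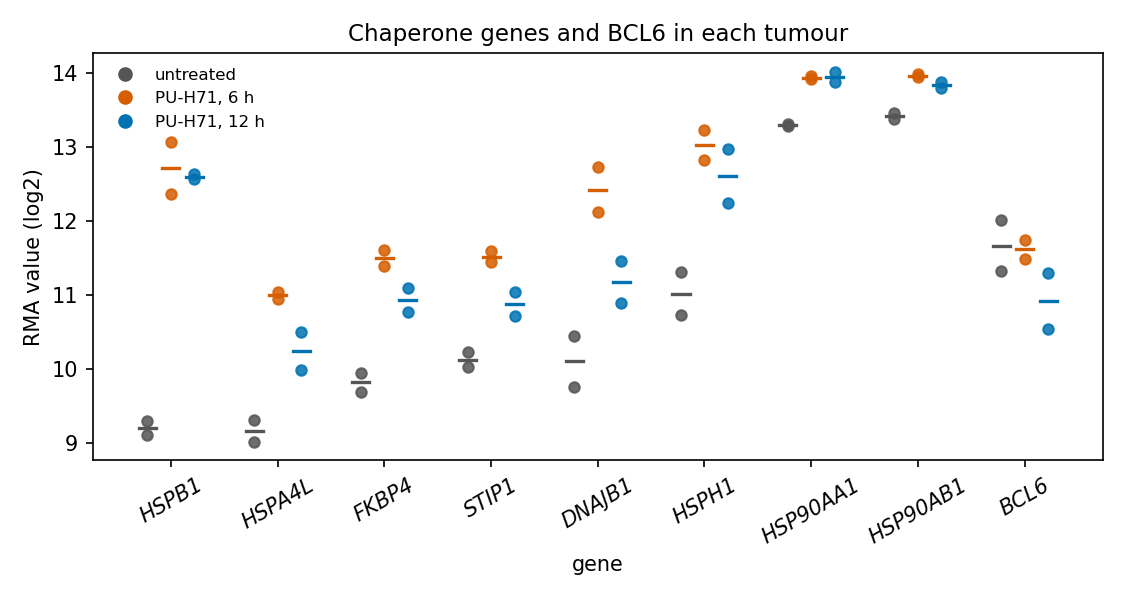
Log2 RMA values (vertical axis) of 8 chaperone genes and BCL6 (horizontal axis) in each tumour, with 1 dot per array and a line at the mean of each group of 2. HSPB1 lies at 9.20 on average in untreated tumours and at 12.71 and 12.60 at 6 h and 12 h, while BCL6 spreads by more within the untreated and 12 h groups than HSP90AA1 does.

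At 6 h 6 lists shifted downwards in the camera test, and none kept the call with a correlation estimated from the arrays (adjusted p = 0.779 with an estimated correlation for each). Nucleolar genes of ribosome biogenesis and MYC targets had a median log2 change of -0.40 over 25 members (camera, adjusted p = 6.18e-09), with 23 members negative. MRTO4, which acts in assembly of the large ribosomal subunit, was at -0.64 (adjusted p = 0.0843), MYC itself at -0.81 (adjusted p = 0.0886) and SRM, the spermidine synthase, at -0.75 (adjusted p = 0.0974). Genes of DNA replication had a median of -0.33 over 39 members (adjusted p = 2.56e-06), with WDR76 at -0.84 (adjusted p = 0.0843) and RFC2, a clamp loader subunit, at -0.46 (adjusted p = 0.115). Proteasome subunits had a median of -0.24, and all 27 members were negative (adjusted p = 5.48e-06), among them PSMA3 at -0.40 and PSMD12 at -0.40. The list called endoplasmic reticulum chaperones here holds genes of the unfolded protein response of that compartment, and not chaperones alone. It had a median of -0.30 over 23 members (camera, adjusted p = 0.00113). SDF2L1 was at -0.92 (limma, adjusted p = 0.119) and PDIA3 at -0.53 (adjusted p = 0.144). Genes of cholesterol synthesis had a median of -0.34 over 17 members (adjusted p = 0.00113), with DHCR7, the last enzyme of the pathway, at -0.67 (adjusted p = 0.0843) and FDPS at -0.49 (adjusted p = 0.118). No member of these 5 lists passed over all genes. In the test adjusted over the list alone, 19 ribosome biogenesis, 10 replication, 9 proteasome, 9 endoplasmic reticulum and 5 cholesterol members fell, and none rose.

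BCL6, a transcriptional repressor of germinal centre B cells and a protein held by HSP90, was at 11.67 ± 0.49 in controls and 11.62 ± 0.18 at 6 h (SD, n = 2), a difference smaller than the spread between the controls (adjusted p = 0.954). Repeated quantile normalization turned its sign, to 0.10, and its other probe sets changed by -0.36 and 0.24. Genes described as repressed by BCL6 shifted downwards, with a median of -0.31 over 20 members and 18 negative (camera, adjusted p = 0.0142; adjusted p = 0.779 with an estimated correlation). None of the members passed over all genes, and adjusted over the list alone 1 fell, MYC, which other lists also hold. CCND2, a D-type cyclin, was at 11.74 ± 0.46 in controls and 9.53 ± 1.49 at 6 h, and CHEK1, a checkpoint kinase, was at -0.36 (adjusted p = 0.127). The shift of this list was lost without 6 h replicate 1 (adjusted p = 0.173).

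At 12 h, HSPB1 alone passed among 14768 genes. It was 10.5-fold above the controls, at 12.60 ± 0.05 (log2 change 3.40 ± 0.22 SE; adjusted p = 0.0204, limma). FKBP4 had a log2 change of 1.11 ± 0.16 and PTOV1 1.07 ± 0.12, neither past the threshold (adjusted p = 0.0897 and 0.0885). HSP90AA1 was at 13.95 ± 0.10 (adjusted p = 0.0897), HSP90AB1 at 13.84 ± 0.06 (adjusted p = 0.112), HSPH1 at 12.61 ± 0.52 (adjusted p = 0.0917) and DNAJB1 at 11.18 ± 0.40 (adjusted p = 0.142). The HSP90AA1 probe set used changed by 0.65, and its others by 0.70, 1.01 and 1.01. BCL6 was at 10.92 ± 0.54, 0.75 ± 0.30 (SE) below the controls, and did not pass (adjusted p = 0.239). Its other probe sets changed by -1.08 and -0.30.

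Other genes with the smallest p-values at 12 h did not pass, with adjusted p from 0.0874 to 0.0897. The lower ones included UNC93B1, which carries Toll-like receptors to endosomes, with log2 change -1.10 ± 0.10, the noncoding RNA LINC01003 at -1.48 ± 0.14, PIGW of glycosylphosphatidylinositol anchor synthesis at -1.16 and ADISSP at -1.05. YIF1A was at -0.96, IMPACT at -1.06, IRS1, the insulin receptor substrate, at -0.86, PAFAH1B3 at -0.78, WDR76 at -1.09 and ACAT2 at -0.85. At 12 h LINC01003, at 5.93 ± 0.04, and IMPACT, at 6.18, were under the dim threshold of 6.19, so the sizes of these changes are uncertain. The higher ones were TEX48 at 1.18, ASB12 at 1.02, CRYZ, a quinone reductase, at 1.00, GNL3L at 0.91, GNAO1 at 0.76, ATM, the DNA damage kinase, at 0.74 and ZNF548 at 0.70. At adjusted p under 0.10 the count was 277, of which 47 were higher and 230 lower. At adjusted p under 0.05, where all 6 arrays gave 1, limma called 0 without either control array, with 1620 and 1457 genes at an unadjusted p under 0.05, 0 without 12 h replicate 1, with 2575 such genes, and 1080 without 12 h replicate 2.

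The heat shock list stayed above the controls at 12 h, with a median of 0.62 over 28 members (camera, adjusted p = 2.71e-16). This call and the 3 that follow were lost with a correlation estimated from the arrays (adjusted p = 0.779 with an estimated correlation for each). Of its members 1 rose over all genes, and, adjusted over the list alone 19 rose and 2 fell, again HSF1 at -0.38 and HSPBP1 at -0.32. DNA replication genes had a median of -0.49, with 38 of 39 negative (adjusted p = 4.48e-12). MCM7, a subunit of the replicative helicase, was at -0.93, E2F8 at -0.83 and RFC2 at -0.71, each with adjusted p = 0.0897. Ribosome biogenesis genes had a median of -0.40 over 25 members (adjusted p = 5.11e-08), with SRM at -0.94 (adjusted p = 0.0900) and ODC1, the ornithine decarboxylase, at -0.66 (adjusted p = 0.0917). Proteasome genes had a median of -0.22, with PSMC3 at -0.61 (adjusted p = 9.29e-04 for the list). The proteasome shift was lost after repeated quantile normalization (adjusted p = 0.154). By the count adjusted over the list alone, 27 replication and 20 ribosome biogenesis members fell, and 0 of the 27 proteasome members passed.

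Mitotic genes had a median of 0.10 at 12 h over 41 members, with 28 positive (camera, adjusted p = 0.00113). This call and the 2 that follow were lost with a correlation estimated from the arrays (adjusted p = 0.779 with an estimated correlation for each). CENPE, a kinetochore motor, was at 0.71 (adjusted p = 0.0917) while MKI67, a marker of cycling cells, was at -0.44 (adjusted p = 0.109). Histone genes had a median of 0.48, with all 10 members positive (adjusted p = 9.29e-04). The genes of MHC class II presentation had a median of -0.44, with all 13 members negative (adjusted p = 0.0113), among them HLA-DRB1 at -0.55 and the invariant chain CD74 at -0.45. None of the members passed over all genes. Adjusted over the list alone, 1 mitotic gene rose, 5 MHC class II genes fell and no histone gene passed. The mitotic shift was lost without 12 h replicate 2 (adjusted p = 0.136) and the MHC class II shift without 12 h replicate 1 (adjusted p = 0.192). Of the 10 histone genes 7 were higher in 12 h replicate 1 than in replicate 2, H3C2 by the most, at 8.25 and 5.91, the latter under the dim threshold of 6.19, while H2BC12 was at 7.765 and 8.444. In the same arrays the actin 3' minus 5' difference was 0.22 ± 0.11 (SD) at 12 h, against -0.11 ± 0.05 in controls.

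**Figure D2:**
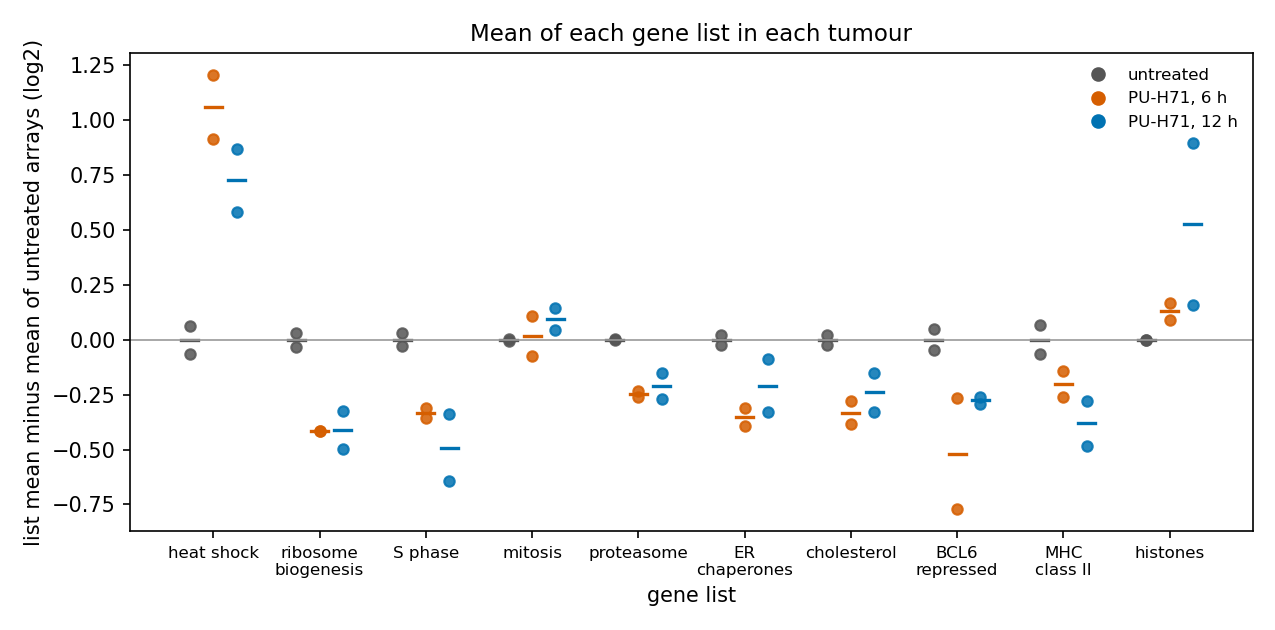
Mean log2 value of each gene list minus its mean over the untreated arrays (vertical axis) for 10 gene lists (horizontal axis), with 1 dot per array and a line at the mean of each group of 2. The heat shock list lies 0.914 and 1.207 above the untreated mean at 6 h and 0.871 and 0.583 above it at 12 h, and the histone list is at 0.897 in 12 h replicate 1 against 0.159 in replicate 2.

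The direct comparison of both times asked which transcripts went on changing. GNL3L, a nucleolar GTPase, was the gene that passed, 2.84-fold higher at 12 h than at 6 h, at 7.40 ± 0.09 in controls, 6.81 ± 0.06 at 6 h and 8.31 ± 0.08 at 12 h (log2 difference 1.51 ± 0.10 SE; adjusted p = 0.0345, limma). The other 3 probe sets of GNL3L changed from control by -0.14, -0.29 and -0.32 at 6 h and by -0.26, 0.10 and 0.15 at 12 h. DLST, SMG1P5, TRMT2B, a tRNA methyltransferase, and ATM were also higher at 12 h, by 1.00, 1.05, 1.00 and 0.80, without passing (adjusted p from 0.0841 to 0.221). BCL2L11, which encodes the pro-apoptotic BIM, was at 9.85 ± 0.08 in controls, 10.78 ± 0.04 at 6 h and 9.40 ± 0.31 at 12 h (difference -1.38 ± 0.15 SE, adjusted p = 0.140). CITED2, a transcriptional co-regulator, had a difference of -1.34 ± 0.15, and PRRG4, THAP9 and TMEM97 had differences of -0.93, -0.78 and -0.77 (adjusted p from 0.140 to 0.306), THAP9 with a 12 h level of 6.07, under the dim threshold of 6.19. BCL6 differed by -0.69 ± 0.30 between the times (adjusted p = 0.672), HSP90AA1 by 0.02 ± 0.10, HSP90AB1 by -0.13 ± 0.10, HSPH1 by -0.43 ± 0.29 and DNAJB1 by -1.24 ± 0.31 (adjusted p from 0.504 to 0.982). The count for this comparison, with 1114 genes at an unadjusted p under 0.05, was 0 in limma without either control array or without either 6 h array, with 655 to 1162 such genes, and 0 without 12 h replicate 1, with 1843. Without 12 h replicate 2 a gene other than GNL3L passed.

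Heat shock genes were lower at 12 h than at 6 h, with a median difference of -0.17 and 22 of 28 negative (camera, adjusted p = 6.68e-05). This call and the 4 that follow were lost with a correlation estimated from the arrays (adjusted p = 0.888 with an estimated correlation for mitotic genes and adjusted p = 0.779 for the other lists). When adjusted over the list alone, 7 were lower, among them BAG3, an HSP70 co-chaperone, at -1.95 ± 0.37, DNAJB4 at -1.44 ± 0.25 and HSPA4 at -0.60 ± 0.14. In controls BAG3, at 5.77 ± 0.11, was under the dim threshold of 6.19, as was DNAJB4. Without _s_at and _x_at probe sets the value of HSPA4 turned sign, to 0.03. The small heat shock gene CRYAB was the 1 higher member, at 1.05 ± 0.28. No member of the other 4 lists passed when adjusted over the list alone. Replication genes were lower again, with a median of -0.15 and 32 of 39 negative (adjusted p = 1.15e-04). Genes of hypoxia and glycolysis (median 0.12, adjusted p = 0.00955), endoplasmic reticulum chaperones (median 0.14, adjusted p = 0.0342) and mitotic genes (median 0.08, adjusted p = 0.0426) were higher at 12 h than at 6 h. No member of the 5 lists passed over all genes. The heat shock difference was lost without 12 h replicate 2 (adjusted p = 0.188), the replication difference without 12 h replicate 1 (adjusted p = 0.966), and the hypoxia difference without 6 h replicate 1 (0.118) or 12 h replicate 1 (0.378). The endoplasmic reticulum difference was lost without 6 h replicate 1 (adjusted p = 0.111), 6 h replicate 2 (0.0691) or 12 h replicate 2 (0.546), and the mitotic difference without 6 h replicate 1 (0.739) or 12 h replicate 2 (0.540).

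Averaged over both times, HSPB1 was again the 1 gene of 14768 that passed (limma, smallest adjusted p = 0.00700), and 10 of 29 lists shifted. Each list call was lost with a correlation estimated from the arrays (adjusted p = 0.849 with an estimated correlation for mitotic genes and adjusted p = 0.779 for the other lists). The heat shock list rose (median 0.75, adjusted p = 1.11e-20), as did histones (0.37, adjusted p = 0.00781) and mitotic genes (0.08, adjusted p = 0.0120). The lists of ribosome biogenesis (-0.41, adjusted p = 6.18e-09), replication (-0.44, adjusted p = 6.37e-10), proteasome (-0.22, adjusted p = 2.33e-05) and endoplasmic reticulum chaperones (-0.31, adjusted p = 0.0113) fell. So did those of cholesterol synthesis (-0.30, adjusted p = 0.0121), genes repressed by BCL6 (-0.32, adjusted p = 0.0205) and MHC class II (-0.30, adjusted p = 0.0418). Adjusted over the list alone, 22 heat shock genes rose and 2 fell, and 21 ribosome biogenesis, 27 replication and 11 proteasome genes fell. In the list-alone count, 6 endoplasmic reticulum, 5 cholesterol, 4 BCL6-repressed and 3 MHC class II genes fell, and no histone or mitotic gene passed. At 12 h cholesterol synthesis (-0.22, adjusted p = 0.110), genes repressed by BCL6 (-0.36, adjusted p = 0.0951) and endoplasmic reticulum chaperones (-0.20, adjusted p = 0.155) did not pass. At 6 h MHC class II (-0.23, adjusted p = 0.254), mitotic genes (-0.002, adjusted p = 0.143) and histones (0.15, adjusted p = 0.116) did not. The test between the times did not pass for cholesterol synthesis (adjusted p = 0.0908), genes repressed by BCL6 (0.702), MHC class II (0.0901) or histones (0.0901). The averaged BCL6-repressed shift was lost without 6 h replicate 1 (adjusted p = 0.0904) or 12 h replicate 2 (0.0911) and the mitotic shift without 6 h replicate 2 (0.0641) or 12 h replicate 2 (0.130). The MHC class II shift was lost without control replicate 2 (0.204) or 12 h replicate 1 (0.116), and the histone shift after repeated quantile normalization (0.0873). The gene count was 1065 at adjusted p under 0.10, of which 193 were higher and 872 lower. Repeated quantile normalization gave 10 higher and 3 lower genes at adjusted p under 0.05 (limma), so the balance depends on the scaling and the threshold. With the threshold at 0.05, where all 6 arrays gave 1, limma called 0 without either control array, with 1554 and 1784 genes at an unadjusted p under 0.05, 0 without 12 h replicate 1, with 3539 such genes, and 1641 without 12 h replicate 2.

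The changes at 6 h and at 12 h went together across genes. Their correlation over 14768 genes was 0.684, and 77.1% of genes had the same sign. Both comparisons use the same controls, and with no change at all in simulated groups the correlation was 0.501 and the share 66.7%. The covariance was 0.0489, against 0.0106 in the simulations, a difference of 0.0383. With 2 controls no split leaves 2 arrays on each side, so part of the excess may come from the shared controls. The simulations used each gene's SD and held no difference in scale between arrays. Upper quartiles were lower in every treated array than in the controls, and this may add to the excess as well. The excess alone therefore does not show a shared response. The correlation is across genes, which are not independent replicates. Without 12 h replicate 1 the correlation was 0.499, against 0.407 in simulations that left out the same array, and without control replicate 1 it was 0.693, against 0.667. Over the arrays left out in turn, the covariance minus its simulated value ran from 0.0235 to 0.0532.

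Markers of other cell types were followed because the host tissue is mouse. Fibroblast markers had median changes of 0.01 at 6 h and 0.06 at 12 h over 16 genes, endothelial markers 0.06 and 0.09 over 8, and myeloid markers -0.07 and -0.08 over 7. T and NK cell markers had medians of 0.02 and 0.08 over 10, red cell markers 0.15 and 0.18 over 6, and markers of skin, muscle and fat 0.01 and 0.01 over 8. B-cell markers had medians of 0.00 and -0.11 over 21 genes, germinal centre markers -0.03 and -0.28 over 15 and plasma cell markers -0.30 and -0.28 over 10. None of these lists passed in any comparison, and no member passed over all genes. MS4A1, the B-cell antigen CD20, was at 13.09 ± 0.05 in controls, 12.72 ± 0.20 at 6 h and 12.94 ± 0.14 at 12 h. COL1A1, a fibroblast collagen, was at 9.74 ± 0.10, 9.49 ± 0.08 and 9.19 ± 0.08, and was the 1 fibroblast gene lower at 12 h when adjusted over the list alone. Its 6 h change turned from -0.257 to 0.385 with the mean of its probe sets. FKBP11, an isomerase of secretory cells, was at 9.98 ± 0.19, 9.28 ± 0.13 and 9.15 ± 0.16. Among plasma cell markers 2 fell at 6 h and 2 at 12 h when adjusted over the list alone.

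Apart from the histone list, which passed at 12 h, the lists that follow did not pass against the controls at either time. Interferon-stimulated genes had medians of -0.23 and -0.42 at 6 h and 12 h, targets of NF-kappaB -0.16 and -0.14, and B-cell receptor components -0.06 and -0.12. The interferon list depended on single arrays. It passed downwards without control replicate 1 (camera, adjusted p = 3.12e-05 at 6 h and 1.85e-05 at 12 h) and, at 12 h, without 12 h replicate 1 (0.00796) or without a filter on dim genes (0.0440). Its direction turned upwards, without passing, without control replicate 2 (0.125 and 0.411), at 6 h without 6 h replicate 1 (0.615) and at 12 h without 12 h replicate 2 (0.670). With an estimated correlation adjusted p = 0.941 at both times. Between the times it passed downwards without 6 h replicate 1 (0.0164) or 12 h replicate 1 (0.00654), and turned upwards without 6 h replicate 2 (0.329) or 12 h replicate 2 (0.199). Averaged over both times it passed downwards without control replicate 1 (8.5e-06) and turned upwards without control replicate 2 (0.228). Histone genes, at a median of 0.15 at 6 h, did not pass there (camera, adjusted p = 0.116) but did without a filter on dim genes (0.0440). They also passed there without either 12 h array, which is 1 check, since both leave-outs give the same 6 h fit. Between the times their median was 0.37 (adjusted p = 0.0901), and they passed without 12 h replicate 2 (6.2e-05), control replicate 1 (0.0452) or a filter on dim genes (0.0259). Without 12 h replicate 1 their direction between the times turned downwards (0.966). Transcripts of kinases known as HSP90 clients had medians of -0.18 and -0.16, BCL2 family genes -0.28 and -0.07, p53 targets -0.07 and -0.04, and immediate early genes -0.05 and -0.03. Targets of NRF2 were at 0.02 and 0.03, targets of ATF4 and CHOP at -0.03 and -0.06, and hypoxia and glycolysis genes at -0.31 and -0.01. In the last list P4HA2 rose at 6 h, while the glycolytic enzymes ENO1, HK2 and ALDOC were at -0.47, -0.54 and -0.43 (adjusted p from 0.111 to 0.118). The chemokine CCL4, an NF-kappaB target, was at 10.96 ± 0.77 in controls and 8.51 ± 0.41 at 6 h (adjusted p = 0.0843). EGFR, a client kinase, was at 8.39 ± 0.02, 9.43 ± 0.34 and 9.77 ± 0.55 in controls, at 6 h and at 12 h (adjusted p = 0.127 and 0.0940). CHEK1, also in the client list, was at -0.64 at 12 h (adjusted p = 0.0897). Of these lists' members, P4HA2 alone passed over all genes. For 6 h, adjusted over the list alone, 1 interferon and 1 p53 gene rose, 2 NF-kappaB, 2 B-cell receptor and 2 immediate early genes fell, and no client kinase or ATF4 target passed. In the same count 3 NRF2 targets rose and 2 fell, 1 BCL2 family gene rose and 2 fell, and 1 hypoxia gene rose and 5 fell. At 12 h, adjusted over the list alone, 4 NF-kappaB genes, 2 immediate early genes and 1 NRF2 target fell, 1 client kinase rose and 3 fell, and 1 hypoxia gene rose.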

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

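The tests of the heat shock list against a 3' shift and against host RNA, and the test of the replication list against fewer cycling cells, were chosen only after the result was seen.

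Values that differed between 6 h and 12 h in a test of the difference itself are GNL3L, 1.505 higher at 12 h on the log2 scale, and 5 gene lists. Each list call was lost with a correlation estimated from the arrays (adjusted p = 0.779 for 4 lists and 0.888 for mitosis) and without at least 1 of the 6 arrays, such as replication without 12 h replicate 1 (adjusted p = 0.966). The GNL3L call was lost without any 1 of the 6 arrays (limma). The median differences of the lists, 12 h minus 6 h, were -0.168 for heat shock, 0.137 for endoplasmic reticulum chaperones, -0.146 for DNA replication, 0.079 for mitosis and 0.122 for hypoxia and glycolysis. Signals outside the tested genes differed from the controls too. A probe set that carries 2 gene symbols, and so names no gene here, was higher by 4.746 at 6 h (adjusted p = 0.0372, limma over all probe sets) and by 4.282 at 12 h (adjusted p = 0.0485). Other probe sets with several symbols passed for the average of both times, in both directions, with log2 changes from -0.901 to 4.378. The 3' minus 5' difference of the actin control probe sets was higher than in controls by 0.225 at 6 h and 0.335 at 12 h. For GAPDH it was higher by 0.125 and 0.224. The 28S control probe sets were higher by 0.342 at 12 h, where the arrays spread by 0.351 (SD, n = 2), and at 6 h were at 8.935 ± 0.163, against 9.015 ± 0.0978 in controls. The 18S control probe sets were not higher, at 6.588 ± 0.097 in controls, 6.296 ± 0.0596 at 6 h and 6.516 ± 0.315 at 12 h.

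The heat shock list was higher after PU-H71 at both times (adjusted p = 0.779 with an estimated correlation). A shift of signal towards the 3' end, larger at 12 h, would put the list at least as high at 12 h as at 6 h. The highest 12 h array lay at -0.0424 relative to the lowest 6 h array, within the pair differences of 0.294 and 0.289, so this shift may still contribute. RNA of mouse host cells would raise host markers, and 39 of them changed by a median of 0.0415 at 6 h, below 0.25 of the heat shock median, which is 0.244. Their median level of 7.16 is low on a human array, so host RNA cannot be told apart from a response to the inhibitor. At 6 h the actin and GAPDH differences rose by 0.225 and 0.125, and the list median by 0.977. For 12 h these values were 0.335, 0.224 and 0.623. The actin and GAPDH differences come from control transcripts and set no bound on how a 3' shift moves other probe sets. They therefore do not decide how much of the rise a 3' shift could account for.

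Replication genes were lower after PU-H71 (adjusted p = 0.779 with an estimated correlation) while mitotic genes were not. Fewer cycling cells could lower both lists, yet the mitosis minus replication difference was higher by 0.25 in the lowest treated array than in the highest control. The mean changes were 0.0564 for mitosis and -0.412 for replication, apart by more than the SD of the mitotic members, 0.216. These values restate the pattern and show only that the mitotic list did not fall along with the replication list. Since the lists need not fall at the same time, they do not decide on fewer cycling cells. A 3' shift would lower the replication list in the array with the larger shift of each pair, and this array differed by -0.306 at 12 h and by 0.0482 at 6 h. With opposite signs in the pairs this stays open, as does a response to the inhibitor.

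The 12 h arrays differed from each other more than the other pairs did. More cells in S phase in replicate 1 would raise its replication list, but replicate 1 minus replicate 2 was -0.306, against 0.0586 and -0.0482 in the other pairs. The actin 3' minus 5' difference was larger in replicate 1, at 0.304 against 0.145, and a 3' shift could lower the list too. Histone genes differed the other way, by a median of 0.818. The replication list therefore does not decide on S phase. More non-polyadenylated RNA could raise 13 small structural RNA genes, which differed by 0.0572, against 0.032 in controls and -0.0879 at 6 h. This gap is small and leaves it open, while the ribosomal control probe sets differed by 0.471 against 0.138 and -0.158. Muscle markers differed by 0.211, under the 0.305 of the control pair, a bound set beforehand against host muscle, but their median level of 6.32 is near the dim threshold of 6.19, a condition added after the values were seen, so muscle stays open.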

How the results depend on the processing

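Array weights and the crossed block were chosen only after the data were seen. The number of arrays limits each value, and with 1 array left in a group that array is assumed to vary like the others. The counts of changed genes were 11 at 6 h, 1 at 12 h, 1 between the times and 1 for the average. The cause was not tested where a count moved, except that pooled or fewer arrays change the spread, and left-out probe sets remove genes, by construction. Without a filter on dim genes all 4 counts were as before, and above the 60th percentile the average gave 5. With all probe sets tested separately limma called 2, 3, 0 and 351 in the order given, the 0 with 2723 at an unadjusted p under 0.05. The mean of a gene's probe sets gave 1, 1, 0 and 281, the 0 with 1008 such genes. Without _s_at and _x_at probe sets limma called 0, 0, 1 and 0, with 1981, 2022 and 2293 such genes beside the counts of 0. HSPB1, the gene called at 12 h and for the average, has only an _s_at probe set and so was left out there. Repeated quantile normalization gave 42 at 6 h and 13 for the average, and centring on medians 1 at 6 h. Only the arrays of the groups compared gave 273 at 6 h and 0 between the times (limma, 861 such genes). Leaving out either array of the third group gave the same counts, since its 1 remaining array adds no spread. Those leave-outs are therefore not separate checks. Restricting the fit to the groups compared could not be run for the average. Array weights gave 698, 1, 0 and 1037, the 0 with 710 such genes. At adjusted p under 0.10 the counts were 256, 277, 2 and 1065, and an intensity trend or a fold of at least 2 changed none by over 1.5 times. Leaving out each array in turn gave 0 to 273 at 6 h, 0 to 1080 at 12 h, 0 to 1 between the times and 0 to 1641 for the average.

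The replicate numbers did not pair the arrays: deviations of same-numbered arrays correlated at -0.24, -0.0503 and -0.0236. That 0 arrays correlated best with their own number follows from these negative signs and adds no evidence. With the replicate block the counts were 1 at 6 h, 1 at 12 h, 0 between the times (limma, 1027 genes at an unadjusted p under 0.05) and 1 for the average. Under the block the histone list passed between the times (adjusted p = 0.0376), against 0.0901 without it. The crossed block gave 84, 1, 1 and 38.

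Of 116 list tests 29 passed, 0 with an estimated correlation (camera, 1 at an unadjusted p under 0.05), 0 with fry (19 such), 46 without a filter, 28 with quantile normalization, 30 with the replicate block and 28 to 49 without each array in turn. The correlation of 6 h and 12 h changes, 0.684, ran from 0.499 to 0.756 without each array, the lowest without 12 h replicate 1, where simulated unchanged arrays gave 0.407.

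Of 5916 alternatives for 381 named results, 5625 kept direction and side of the threshold, 101 lost the call, 159 gained it and 31 reversed, of which 0 were of the 13 called results. Only the 13 called results could lose a call, so most of the 5625 were results that were not called to begin with. Of the 13, centring on medians lost 10, and the replicate block or all probe sets tested separately lost 11 each. Leaving out either control array lost every call, and leaving out either 6 h array lost most of them. No filter on dim genes, an intensity trend and repeated quantile normalization kept all 13. The cause was not tested. Reversed log2 changes with the mean of a gene's probe sets were COL1A1 0.385 at 6 h, CD5 0.016 and MDM2 -0.130 at 12 h, and BUB1 -0.003, CA1 -0.118, H2BC5 0.034 and HSP90AA1 -0.048 between the times. With quantile normalization they were AIF1 0.003 and BCL6 0.102 at 6 h and CD5 0.020 at 12 h. Without _s_at and _x_at probe sets they were HBB -0.065, MDM2 -0.141 and RASGRP3 0.105 at 12 h, and COL3A1 0.040, FKBP11 0.007, HBB -0.194, HSP90AA1 -0.060 and HSPA4 0.026 between the times. Over the arrays left out in turn, BCL6 at 6 h ran from -0.396 (without control replicate 1) to 0.291 (without control replicate 2), and was 0.072 without 6 h replicate 2. DES ran from -0.365 to 0.057 (without control replicate 1) and KRT10 from -0.679 to 0.073 (without 6 h replicate 1). Between the times, the values reversed without 12 h replicate 1 are the lower ends for ENG, -0.059 to 0.371, H1-2, -0.056 to 1.582, H1-4, -0.016 to 1.628, HBB, -0.064 to 0.447, and HSP90AA1, -0.052 to 0.082, which was also -0.010 without 6 h replicate 1. Without 12 h replicate 2 the reversed ends were BST2 0.044 (lowest -0.488), ISG15 0.115 (lowest -1.172) and MSMO1 -0.061 (highest 0.659).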

Other observations

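Every gene in this part was picked only after its values were seen, and no test was run beyond those already given. Several transcripts were lower at 6 h than in the controls or at 12 h. DLST was at 10.04 ± 0.02 in controls, 9.20 ± 0.07 at 6 h and 10.20 ± 0.10 at 12 h (SD, n = 2), and TRMT2B at 8.26 ± 0.04, 7.46 ± 0.10 and 8.46 ± 0.07. U2AF1 was at 12.06 ± 0.01, 11.10 ± 0.04 and 11.74 ± 0.16, still below the controls at 12 h. ME1, the cytosolic malic enzyme and an NRF2 target, went the other way, at 7.35 ± 0.34, 9.53 ± 1.06 and 7.21 ± 0.15, with 10.28 and 8.78 in the 6 h arrays. None of these passed over all genes.

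Interferon-stimulated genes spread widely within groups. IFI44L was at 8.15 and 9.76 in the controls, 6.47 and 8.96 at 6 h and 8.59 and 6.70 at 12 h. CXCL10, a chemokine induced by interferon, was at 12.20 and 10.10, 7.44 and 9.50, and 10.24 and 11.23. The 12 h arrays also differed in the embryonic globin HBE1, at 14.07 and 11.64, and in MYBL1, a germinal centre marker, at 6.00 and 8.19. In the histone list 7 of 10 genes were higher in 12 h replicate 1, with a median difference of 0.818.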
